A study of Mus musculus with 4 samples.

How the data were processed

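The series used chromatin immunoprecipitation followed by sequencing (ChIP-seq): DNA bound by a protein is pulled down with an antibody and sequenced, and places with more reads than a control are called as peaks. Per the labels' protocols, the libraries were made for single-end Illumina sequencing. Samples were grouped by their titles into 1 immunoprecipitate of GFP-tagged Tbx20 and 3 whole heart inputs. The inputs have no values used here, so whether they were pooled, and how they were weighted, is not known.

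The authors called peaks with QuEST, a peak caller that smooths read positions into a density, and deposited the accepted peaks with a score per peak, which per the note accompanying the deposited list is a normalized read number and comes from the field that QuEST names ef. The note does not say what the score was normalized by, so the main results use the score only to describe, rank and filter peaks within this list. The other observations also read it as height over input, as a hypothesis. The positions are on mm9, per the submitters' processing notes, and are given as deposited, so a start may count from 0. The aligner, the read filters, the thresholds and the version of the peak caller are not given in the sources used here. Read totals were not used here, so intervals could be given only for counts of peaks, and these cover counting error only.

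Before the data were examined, 6 tests were fixed. The distance of peaks to transcription start sites, the test of 16 gene lists near peaks, the test of 22 sequence motifs and of all 6-base words in peak centres, and the relation of the T-box motif to score all need the sequence or annotation of mm9. The gene table at hand was on another assembly and coordinates were not carried between builds, so these 5 tests were not run. The description of the peak set and the test of peak spacing were made as fixed, with random positions drawn between the first and last peak of each chromosome, the form fixed for the case without a genome. This draw ignores assembly gaps and regions where reads cannot be placed. Of the rule fixed for naming items, the part on the 15 highest-scoring peaks could be applied, without nearest genes. The parts on genes could not. Tbx20 itself is named below, but no peak was assigned to it. Every other peak given by position was chosen after its values were seen, because it had the highest or lowest score or the greatest width of a group described, and the runs given by position were chosen for their number of peaks.

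The spacing test counted peaks whose midpoint lay within 10 kb of another midpoint, in the data and in 1000 draws, and doubled the smaller tail. It was tested on simulated data with the same number of peaks per chromosome. It called 0 of 20 sets without clustering and 20 of 20 sets in which 200 of the 4012 peaks were moved next to another. The sets without clustering used the same uniform draw as the test, so false calls under assembly gaps or uneven density were not checked. The ceiling of a score is the highest score from that place in the list onward, and a peak within 2% of it was counted as at the ceiling. On simulated lists in which 20.9%, 34.4% and 59.2% of peaks had the lowest input, 20.9%, 34.5% and 59.2% came out at the ceiling. These lists were sorted by height and kept every other input clearly above the lowest. They therefore checked the calculation only, and not whether the deposited scores arise in this way. The shift of peaks within 500 kb, the ceiling, the runs of peaks (midpoints at most 50 kb apart) and the comparisons of chromosomes X and Y were chosen after seeing the data. So were the relations between width, score and place in the list. Groups of peaks were compared by permuting peaks 100000 times, two-sided. Percent of the ceiling was compared first by medians and then by mean log2, a statistic chosen after the permuted medians were seen to pile up at 100%, and both results are given. Such tests describe the peaks of 1 sample and say nothing about variation between animals. Alternatives were the 2006 better-scoring peaks, the first 2006 in the list, peaks within 500 bp merged, a distance of 50 kb, other gaps between peaks of a run, and other tolerances for the ceiling. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.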

Results

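Tbx20 is a T-box transcription factor needed for heart development and for the function of adult heart muscle. The series mapped where a Tbx20 protein fused to green fluorescent protein (GFP) was bound in the adult mouse heart. Chromatin from whole hearts of CD1 mice aged 2 months was immunoprecipitated with a goat antibody against GFP and sequenced. The design names whole heart input DNA as the control. The labels list 1 immunoprecipitated sample and 3 inputs, and they give the inputs an embryonic age, E11.5 for inputs 1 and 2 and E9.5 for input 3, whereas the immunoprecipitated hearts were adult. The values analysed here are the authors' peak list of the 1 immunoprecipitated sample. There is no replicate, so no value below has an error between animals, and the read depth behind the peaks is unknown.

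The comparison of the immunoprecipitate with input gave 4012 peaks on chromosomes 1 to 19, X and Y, which together covered 1.03 Mb of the mm9 genome. The peaks were narrow, with a median width of 226 bp, an interquartile range of 166 to 306 bp and extremes of 128 and 1802 bp. The authors' score per peak, which their notes describe as a normalized read number from the peak caller, had a median of 22.7 and an interquartile range of 11.3 to 35.0, and ran from 3.00 to 294. The peaks were not assigned to genes, because no annotation on the mm9 build was used here, and are named by their positions as deposited.

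The highest-scoring peak lay on chromosome 9 from 7270138 to 7270420 and had a score of 294, well above the next. The second, at 186, was also on chromosome 9, from 119378811 to 119379134. Chromosome 2 held the next pair, a peak from 128013152 to 128013502 with a score of 180.1 and a peak from 103118058 to 103118308 with a score of 176. They were followed by a peak on chromosome 4 from 123132532 to 123132844 at 173, a peak on chromosome 10 from 20206541 to 20207204 at 171 and a peak on chromosome 15 from 86002550 to 86002928 at 166. The peak on chromosome 18 from 40412367 to 40412764 scored 159.6 and that on chromosome 12 from 107396861 to 107397392 scored 159. A peak on chromosome 7 from 56488441 to 56488875 reached 156, a peak on chromosome 1 from 137454550 to 137454955 reached 154 and a peak on chromosome 16 from 43610476 to 43610703 reached 153. The last of the 15 highest were on chromosome 17 from 73371706 to 73372446 at 152, on chromosome 16 from 5431235 to 5431562 at 151 and on chromosome 1 from 76079918 to 76080223 at 151. A peak on chromosome 7 had the same score as the last of these and was left out because it came later in the list. These 15 peaks were spread over 11 chromosomes and were 227 to 740 bp wide. None of the 15 had another peak within 10 kb, and the median distance to the nearest other peak was 108 kb.

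Peak width rose with score across the 4012 peaks of this sample, weakly, with Pearson's r = 0.17 and Spearman's rho = 0.17 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Width followed the order in which the authors listed the peaks more closely, with r = -0.35 and rho = -0.44 (permutation p = 1e-05). Score fell along the list with r = -0.45 and rho = -0.38 (permutation p = 1e-05). Leaving out the 2 peaks farthest from the median on the first measure of each relation gave r = 0.18, -0.36 and -0.45. These 3 relations are across peaks, which are not independent replicates, and their Benjamini-Hochberg adjusted permutation p-values were also 1e-05.

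The order of the list bounded the scores. A ceiling was defined for each peak as the highest score among that peak and all peaks listed after it. In total 1448 of the 4012 peaks, 36.1%, had scores within 2% of this ceiling, which fell from 294 at the first peak to 30.0 near the end of the list. With the order of the list shuffled 1000 times, at most 20 peaks lay within 2% of the ceiling. Such a shuffle removes every link between score and place, so it does not test how the scores came to be bounded. The other 2564 peaks lay below it, at a median of 33.7% of the ceiling (interquartile range 21.1 to 45.4%), and only 108 fell between 80% and 98% of it. The first 15 peaks in the list and the 15 with the highest scores shared 3 peaks. The peak at place 4 of the list, on chromosome 7 from 118941153 to 118941483, had a score of 34.2, whereas 14 of the 15 highest-scoring peaks lay at the ceiling.

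**Figure D1:**
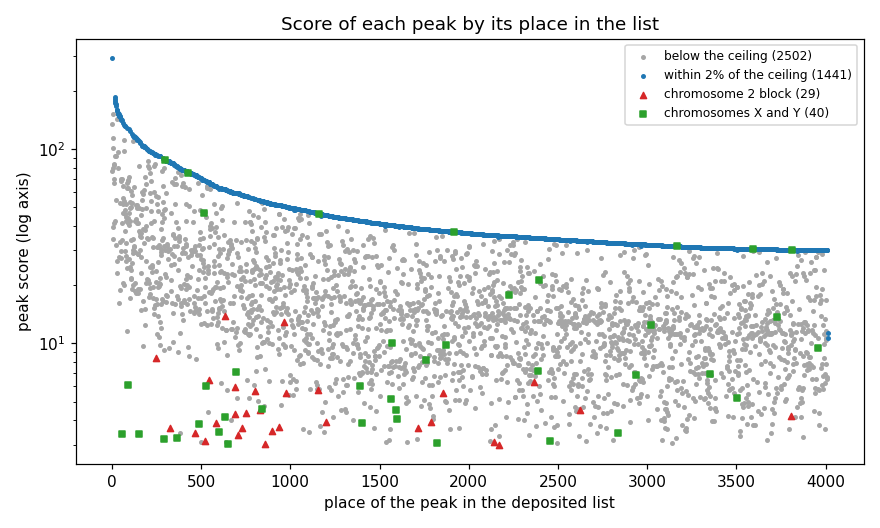
Score of each of the 4012 peaks (log axis) against its place in the authors' list. Blue points are autosomal peaks within 2% of the ceiling, grey points are other autosomal peaks, red triangles are the 29 peaks of a dense run on chromosome 2 and green squares are the 40 peaks on chromosomes X and Y; the ceiling falls from 294 to 30.0 near the end of the list, and no red triangle reaches it.

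The autosomes held 3972 of the peaks, at 1.67 per Mb between the first and the last peak of each chromosome (95% Poisson interval 1.62 to 1.73, for counting error only). Among autosomes, density was highest on chromosome 11, at 2.19 per Mb (1.93 to 2.47), and lowest on chromosome 3, at 1.32 per Mb (1.15 to 1.52). These intervals do not overlap, but both chromosomes were picked as the extremes and the intervals treat peaks as independent. Chromosome X held 27 peaks over 160.3 Mb, which is 0.168 per Mb (0.111 to 0.245), 9.93 times lower than the autosomal density. Its share of all peaks was 0.673% (exact Clopper-Pearson 95% interval 0.444 to 0.978%). Chromosome Y held 13 peaks within 1.48 Mb, or 8.79 per Mb (4.68 to 15.04) of the short stretch between its first and last peak.

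The median score was 22.9 on autosomes, 7.06 on chromosome X and 5.22 on chromosome Y. The value for chromosome X rested on 10 peaks that lay in 3 runs of 3 or more with gaps of at most 50 kb, whose median score was 4.02, and the other 17 had a median of 21.2. Scores under 5 were found at 169 of the 3972 autosomal peaks, 10 of the 27 peaks on chromosome X and 5 of the 13 on chromosome Y. The highest-scoring peak of chromosome X, from 11520614 to 11520845, had a score of 87.7. On chromosome X, 7 of the 27 peaks lay at the ceiling, against 36.3% of autosomal peaks. All 7 were among the 17 peaks outside the runs, and the 10 in runs reached at most 38.7% of the ceiling. No peak on chromosome Y lay at the ceiling, and their scores ran from 3.05 to 10.01.

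**Figure D2:**
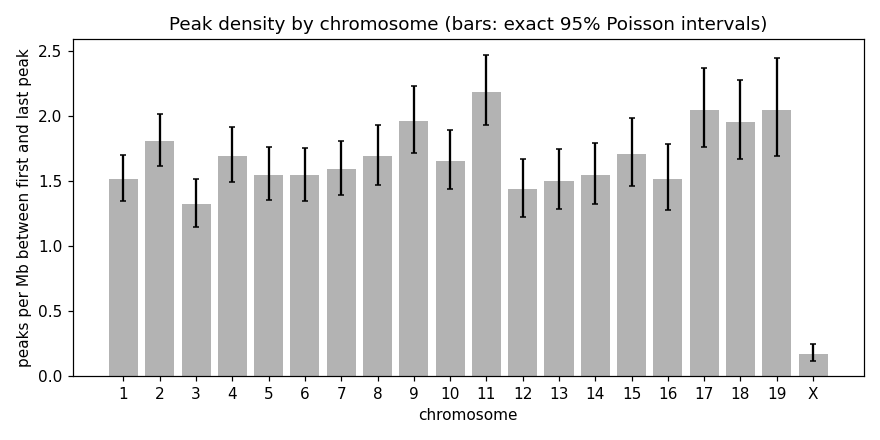
Peaks per Mb between the first and last peak of each chromosome, with exact 95% Poisson intervals as error bars. Chromosome X (0.168 per Mb) lies below every autosome, and chromosome Y is left out because its 13 peaks span only 1.48 Mb.

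Peaks lay closer together than positions drawn at random. Of the 4012 peaks, 456 (11.4%) had another peak within 10 kb, midpoint to midpoint, against 3.34% ± 0.409 (SD over 1000 draws) when positions were drawn uniformly between the first and last peak of each chromosome, a ratio of 3.41 (two-sided permutation p = 0.002, the smallest that 1000 draws can give). The observed share was above the 4.91% of the highest draw. The median distance to the nearest peak was 111 kb, against 207 kb in the draws. Each peak was also moved at random within 500 kb of its place, which keeps density differences over megabases but not over shorter distances. Then 5.44% of peaks had a neighbour within 10 kb, so the observed share was still 2.09 times higher (two-sided permutation p = 0.002). As a ratio, the excess over uniform positions was largest at the shortest distance, with 2.12% of peaks (85) within 1 kb of another against 0.341%. Peaks within 500 bp were not merged for this, so a region called as several peaks could add to the excess at 1 kb. As a difference in percent, the excess over uniform positions was largest at 100 kb, at 47.9% against 28.7%, among the 9 distances computed. At 500 kb the shares were 86.8% and 80.8%. Peaks shifted within 500 kb gave 39.7% at 100 kb and 85.8% at 500 kb, so part of these excesses goes with density over megabases.

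**Figure D3:**
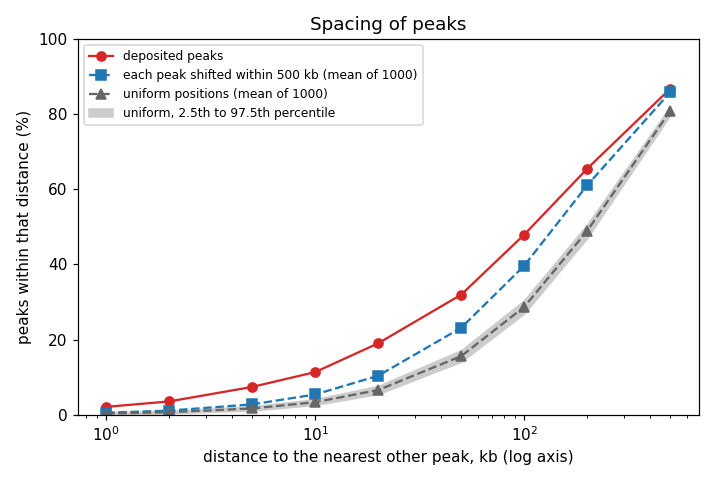
Percent of peaks whose nearest other peak lies within a given distance (log axis, kb), for the deposited peaks (red), for peaks shifted within 500 kb (blue, mean of 1000 draws) and for uniform positions (grey, mean of 1000 draws, band for the central 95% of draws). At 10 kb the values are 11.4%, 5.42% and 3.37% in the draws made for this plot.

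Joining peaks whose midpoints were at most 50 kb apart gave 2729 single peaks, 450 runs of 2 and 107 runs of 3 or more, which together held 383 peaks. The longest run, on chromosome 2 from 77707842 to 77859882, held 29 peaks in 152 kb. The next, on chromosome 9 from 24511738 to 24694232, held 14 peaks in 182 kb. No other run held more than 6 peaks. In 1000 uniform draws the longest run of any draw held 8 peaks. In 1000 draws with each peak shifted within 500 kb, the longest run held a median of 9 peaks and at most 23. Thus 14 peaks lay within the range of these draws and 29 above it. Such draws leave the peaks of a dense run near one another, and their longest run could lie on any chromosome. The range therefore does not test the run on chromosome 9 in its own region.

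The runs differed in their peaks. The run on chromosome 2 had broad peaks, with a median width of 602 bp and the widest peak of the list at 1802 bp (from 77742541 to 77744343), and its scores were low, with a median of 4.23 and a range of 3.00 to 13.8. All 29 of its peaks lay below the ceiling, at a median of 8.59% of it. The run on chromosome 9 had a median width of 306 bp, a median score of 15.2 and a range of 5.22 to 41.4, and 4 of its 14 peaks lay at the ceiling. Chromosome 9 also carries the Tbx20 gene, but the position of the gene on mm9 was not matched to this run. The longest of the other runs held 6 peaks in 36.4 kb on chromosome 14 from 35362547 to 35398922, with scores of 14.8 to 143. Runs of 5 peaks lay on chromosome 16 from 33581097 to 33607429, with a median score of 30.2, and on chromosome 1 from 173458086 to 173509477, with a median score of 4.38. All 29 peaks of the run on chromosome 2 scored below the 22.7 at which the 2006 better-scoring peaks start, so none is among these.

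**Figure D4:**
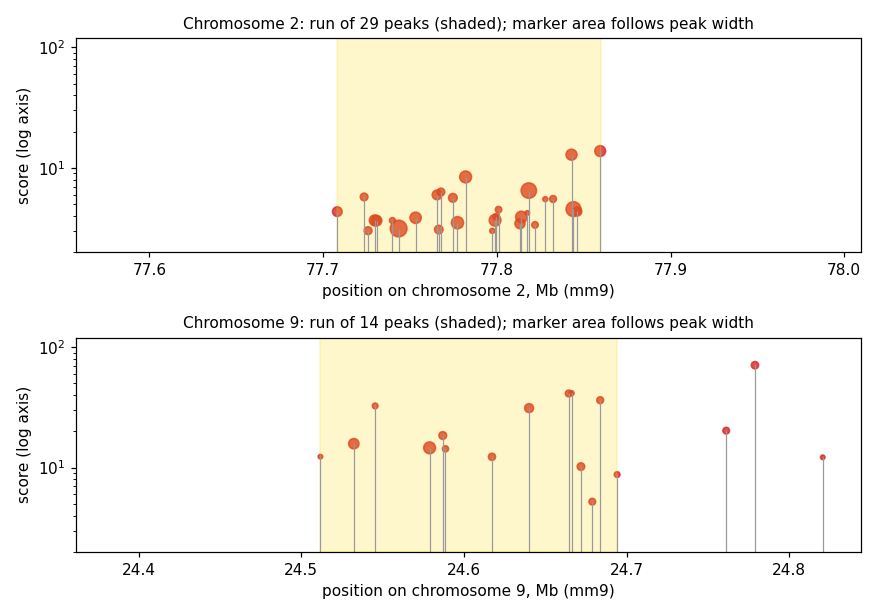
Peaks around the 2 longest runs (shaded), by mm9 position in Mb and score (log axis); marker area follows peak width. The 29 peaks on chromosome 2 have scores up to 13.8, and the 14 on chromosome 9 up to 41.4.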

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

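Peaks were closer together than random positions under every alternative run (two-sided permutation p = 0.002 in each): the share with a neighbour was 9.98% after merging peaks within 500 bp, 5.73% among the 2006 better-scoring peaks and 32.0% at a distance of 50 kb, and, in settings chosen after seeing the data, 10.6% without the runs on chromosomes 2 and 9, 11.1% without chromosomes X and Y and 9.82% among the first 2006 peaks listed. The excess over uniform draws was 5.75 times for the first 2006 listed and 3.35 times for the 2006 better-scoring peaks. The count of peaks moved from 4012 to 2006 by construction when only the better-scoring ones were kept, with a median width of 236 bp, and to 3977 when peaks within 500 bp were merged. The longest run was 29 peaks with gaps of at most 20, 50 or 100 kb, 23 after merging, 24 among the first 2006 listed and 4, elsewhere, among the 2006 better-scoring peaks, which by construction hold none of the 29. That on chromosome 9 depended on the setting: 6 peaks with gaps of at most 20 kb, 17 with 100 kb, 14 after merging, 5 among the first 2006 listed and 4 among the better-scoring ones. The share of peaks at the ceiling was 35.7% with a tolerance of 0.1% and 37.2% with 10%. The lower percent of the ceiling on chromosome X weakened from -1.13 to -0.195 in mean log2 (permutation p = 0.433) without its runs of 3 or more peaks, also chosen after seeing the data. Ranking by place in the list kept 3 of the 15 highest peaks. With 1 immunoprecipitate, no replicate could be left out and no label permuted. The alternatives for start sites, gene lists, motifs, 6-base words and motif strength were not run, since they need the sequence or annotation of mm9.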

Other observations

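The tests in this part were chosen after the data were seen, except that of merging. Those of regional density and of the ceiling beside a close neighbour were chosen before their own results, and the others after the result was seen. Outside the runs on chromosomes 2 and 9, the 421 peaks with another peak within 10 kb were wider than the 3548 isolated ones (median 265 against 221 bp, permutation p = 1e-05) and had a higher ceiling (median 39.8 against 36.4, a log2 difference of medians of 0.129, permutation p = 2e-05). Their scores did not differ detectably (median 21.4 against 23.2, permutation p = 0.428). These permutations treated the 421 peaks as independent, although each of them lies beside another peak. On the hypothesis that the ceiling tracks the height of the immunoprecipitate, peaks with a close neighbour would be taller, by a small margin. They also lay at a lower percent of the ceiling (median 45.16% against 50.06%), and fewer were at it (31.83% against 36.92%), differences that were not tested. If the score is height over input, these would go with higher input, so stronger binding at such peaks was not shown. At 10 kb, neither density differences over megabases nor peaks split within 500 bp gave the spacing seen. Shifting peaks within 500 kb left 5.443% with a close neighbour against the 11.4% observed (two-sided permutation p = 0.002). Merging peaks within 500 bp left 9.982% against 3.29% in draws (two-sided permutation p = 0.002). Density that varies over shorter distances, and a region called as several peaks farther apart, were not tested.

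The falling ceiling of the scores bears on any ranking by them. Of the 1448 peaks at the ceiling, 98.76% had scores that were whole multiples of a step of 0.0585, within 0.03 of a step. By chance, 6% would for a step fixed beforehand, but this step was fitted to these same ceiling scores. Scores of this kind could arise from dividing the height of the immunoprecipitate by an input value held at 1 floor where input is low. Peaks would then be listed by height, with thresholds near 30 for height over the floor and near 3 for the ratio. On this hypothesis the score of a ceiling peak is a lower bound that depends on the floor, and 36.1% of the list is ranked by height alone. A read number scaled by 1 constant for all peaks is argued against, since it would put both groups on the same steps, whereas 6.084% of the peaks below the ceiling lay on them. A scaling other than input that differs between peaks was not tested.

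If the score is height over input, a hypothesis for which no input values were used, the run of 29 peaks on chromosome 2 may reflect DNA that is present in more copies in these CD1 mice than in the reference. Its scores were a lower percent of the ceiling than those of the other peaks, by -2.42 in mean log2, or 5.35-fold (permutation p = 1e-05, Benjamini-Hochberg adjusted p = 1e-05 over the 4 tests of this statistic). A permutation of the difference of medians, run first, gave p = 0.0795 and so did not pass 0.05. The mean log2 was chosen after that result, because permuted medians pile up at 100%, and both permutations treat the 29 neighbouring peaks as independent. On that reading of the score, binding alone over DNA with ordinary input is argued against by its median of 8.59% of the ceiling, below the 33.7 to 100% of random peak sets of that size, but binding on extra copies remains open. With another scaling of the score, binding alone stays open too. A low percent of the ceiling was not particular to the run on chromosome 2. Medians were 13.3% in the run of 5 on chromosome 1, 7.79% in the chromosome X runs and 12.6% on chromosome Y. The runs on chromosomes 14 and 16 had 64.9% and 52.4%. Extra copies were not told apart from other sources of high input. For the run on chromosome 9, the median of 46.18% was within the 29.1 to 100% of random sets, a wide range that binding over ordinary input would meet, and the mean log2 difference of 0.0245 (permutation p = 0.93, against -2.77 percentage points and permutation p = 0.893 for medians) neither showed nor excluded a modest gain of copies shared with the inputs. A gain present in the tagged mice only, such as a transgene carrying the region, was not tested and stays open too.

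The shortage of peaks on chromosome X is a further pattern to follow. The autosomal density would give 268 peaks on it, and 27 were seen (95% Poisson interval 17.8 to 39.3). If the hearts carried 1 copy of chromosome X and heights were therefore 2 times lower, the 16.6% of autosomal peaks whose ceiling is at least 2 times the lowest one would predict 44.5 peaks. The interval lies below both 44.5 and 268, so neither prediction was met. That 44.5 is nearer to the 27 seen carries no weight, because any loss of height lowers the expected count. The interval also treats the 27 peaks as independent, although 10 of them lay in runs. The prediction of 44.5 takes the ceiling as height and every heart as having 1 copy, so the test did not decide the cause. The sex of the hearts is not in the labels. The 13 peaks on chromosome Y could come from male DNA among the hearts, but reads of similar sequence from elsewhere were not excluded. The share of male hearts is unknown. Their number is not what 1 copy at lower height would give. They lay at 8.79 per Mb of a short stretch, against 1.67 per Mb on autosomes, and none was at the ceiling. On the same reading of the score, some of the peaks that were called may come from regions of high input: chromosome X peaks were at a lower percent of the ceiling than autosomal ones, by -1.13 in mean log2 (permutation p = 1e-05, against p = 0.133 for the difference of medians). This rested on 10 peaks in 3 runs of 3 or more, with scores of 3.03 to 12.4, which are not independent. The other 17 peaks, at a median of 60.9% of the ceiling against 49.5% on autosomes, differed from autosomal ones by -0.195 in mean log2 (permutation p = 0.433), which leaves their input open. Chromosome Y peaks were lower by 4.04-fold (permutation p = 1e-05, against p = 0.185 for medians). Lower binding on chromosome X as biology was not tested.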
